A study of Mus musculus with 12 samples.

How the data were processed

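The samples were leptotene/zygotene (LZ) and pachytene spermatocytes of C57BL/6 mice, sorted by fluorescence-activated cell sorting with a check of purity, per the labels. LZ and pachytene are successive stages of the first meiotic prophase. Cells were labelled wild type (WT) or Rnaseh1 knock-out (KO-labelled in the text), which gave 4 groups of 3 libraries, 12 in all. Polyadenylated RNA was amplified as cDNA and sequenced as paired ends. RNase H1 is an enzyme that degrades the RNA strand of RNA:DNA hybrids, including those in R-loops.

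Per the labels, reads were processed with TopHat2 2.1.1 and Cufflinks 2.2.1 on the mouse genome build mm9. The deposited values are FPKM per gene (fragments per kilobase of transcript, relative to all mapped fragments), which the authors scaled between libraries by ERCC spike-in RNA. The annotation, any filter and the formula of the scaling are not stated. The table holds 23235 genes, 12 library columns and 4 columns without a name. Each of these 4 equals a mean of library columns within a relative difference of 6.47e-08: the WT LZ, KO-labelled LZ and WT pachytene groups, and KO-labelled LZ replicates 1 and 3 without replicate 2. The unnamed columns were not used in any comparison. The table has 0 ERCC entries and holds 0 of the 13 mitochondrially encoded genes that were listed, so that list has no result.

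Read counts are not in the table, so the depth of each library is unknown and neither intervals nor limits of detection that rest on counts are given. All values of at least 1 in each library divide by a common factor to numbers of 6 significant digits, within 0.1 of the last digit, and the ratios of the 12 factors are those of whole numbers between 22 and 326 within 1.74e-16. Dividing by the factors gave FPKM before the scaling, with totals of 810415 to 992206 per library.

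Genes were kept at a value of at least 1 in at least 3 of the 12 libraries, which left 15400. Values were transformed as log2(value + 1). A model with 1 mean per group was fitted to all 12 libraries in limma 3.58.1 under R 4.3.3, with moderated variances that follow the mean level, and contrasts between groups were read from it. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were KO-labelled against WT at each stage, pachytene against LZ in each genotype, the difference between the KO effects of the stages (interaction), and the KO effect averaged over stages. The spike-in scaling of the authors was kept. Because the median log2 change of all genes lay far from 0, changes are also given relative to that median, and counts are also given after each library was divided by its median ratio to the geometric mean of all libraries (median-ratio scaling).

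Gene lists were fixed for leptotene and zygotene, pachytene and A-MYB targets, round spermatids, spermatogonia, Sertoli cells, Leydig cells, peritubular and endothelial cells, blood and macrophages, meiotic recombination, the synaptonemal complex and chromosome axis, ATR and the DNA damage response, p53 targets, R-loop factors, mitochondrially encoded genes, maintenance of mitochondrial DNA, nuclear oxidative phosphorylation (OXPHOS) genes, the piRNA pathway, replication and S phase, G2/M and metaphase I, the interferon response, stress and immediate early genes, X-linked reporters of meiotic silencing, Y-linked genes, retrogenes active at pachytene, cytosolic ribosomal proteins, spermatogenesis transcription factors and histones. Some genes stand in more than 1 list. Members called in each direction were counted over all genes tested and adjusted over the list alone. Lists and the X and Y chromosomes were tested with camera of limma, with a preset correlation between genes of 0.01 and then with an estimated one, adjusted over all lists of a comparison. The chromosome of 22979 genes was taken by symbol from the RefSeq table of assembly GRCm38.p6. This is a later build than mm9, so it gave names and chromosomes only and no positions are reported.

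The named genes followed a rule. In the KO-labelled against WT comparisons and in the WT stage comparison, Rnaseh1 came first. The 8 highest and the 8 lowest log2 changes followed, among called genes with a mean of at least 5 in the higher group, with all 3 libraries of one group above all 3 of the other, and without predicted or unnamed gene models. From each list came up to 4 called members with the largest absolute change, or up to 2 measured members with the highest mean where none was called. For the interaction, the 5 smallest p in each direction were taken. Names are those of the table. Genes outside the rule are said to be so where they appear.

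Totals, shares and scores per library were compared between groups by exact two-sided permutation tests, in which 3 against 3 libraries give a p of at least 0.1. The stage score of a library is its mean log2(value + 1) over the pachytene and A-MYB list minus that over the leptotene and zygotene list. Overlaps of called genes were tested with Fisher's exact test. The groups, comparisons, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the following. The repeat of each result on FPKM before the scaling was chosen after seeing the data. Explanations of patterns in the closing section were tested for patterns already seen. The tests named so there were chosen only after their own result was seen. The other alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5, median-ratio scaling, quantile normalisation, a fit of only the groups compared, replicate numbers as a block, no trend of the variance, quality weights per library, a minimum of 2-fold, an estimated correlation for the set tests, and leaving out each library in turn.

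The fit was tested on simulated data with the residual spread of these libraries. Of 100 genes changed 2-fold, it called 24% in the KO-labelled against WT comparison at LZ and 27% at pachytene, and of 100 genes changed 4-fold it called 91% and 88%. At most 0.0592% of unchanged genes were called. Camera called 10 of 10 raised lists and 0 of 10 unchanged lists in each comparison. Changed genes and list members were taken only from genes with a higher mean level, and far fewer genes were changed than were called in the data. The rates therefore do not cover genes of low level or comparisons in which many genes change. Simulated genes were drawn independently of each other and without shifts of whole libraries. In the data the estimated correlation within a list reached 0.801, so these rates do not cover genes that move together. Paralogs share reads, and how these were divided between members of a gene family is not stated. Identical values were looked for between libraries, with 0 identical pairs found.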

Results

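RNA of mouse spermatocytes was measured in 12 libraries, 3 in each of 4 groups: WT LZ, KO-labelled LZ, WT pachytene and KO-labelled pachytene. During leptotene and zygotene, DNA breaks form and homologous chromosomes begin to pair. At pachytene the homologs are synapsed and the X and Y chromosomes are silenced. The table gave spike-in-scaled FPKM for 23235 genes, of which 11146 to 15290 had a value of at least 1 in a library. The depth of the libraries is unknown. Values below are means ± SD in spike-in-scaled FPKM over the 3 libraries of a group (n = 3). Log2 changes carry the standard error of limma (SE). The labels do not state that replicates came from separate animals. The p of single genes in limma and of the permutation tests thus measure the spread between these libraries. Camera and Fisher's exact test compare genes with genes, and the exact binomial tests use whole numbers summed over libraries. Their p do not measure that spread. Correlations of log2 values across genes were 0.969 to 0.973 within the WT LZ group and 0.967 to 0.975 within each of the pachytene groups. They were lower within the KO-labelled LZ group, at 0.923 to 0.952.

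On the spike-in scale the summed level was far higher in pachytene than in LZ libraries, and the genotypes differed in opposite directions at the 2 stages. The sum over the 15400 genes tested was 763700 ± 140100 in WT LZ libraries and 469900 ± 42530 in KO-labelled LZ libraries, a ratio of 0.615. At pachytene it was 3842000 ± 462800 in WT and 5753000 ± 942100 in KO-labelled libraries, a ratio of 1.5. All 3 libraries of one group lay above all 3 of the other in both cases, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The median over genes was 25.6 ± 3.14 in WT and 27.3 ± 1.62 in KO-labelled pachytene libraries, a ratio of 1.07 (exact permutation p = 0.4). After median-ratio scaling the ratios of the sums were 0.937 at LZ and 1.16 at pachytene. The number of cells per library is not stated, so the sums are not per cell. The scaling formula and the depth of each library are unknown, so a part of depth in the sums is not excluded.

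**Figure D1:**
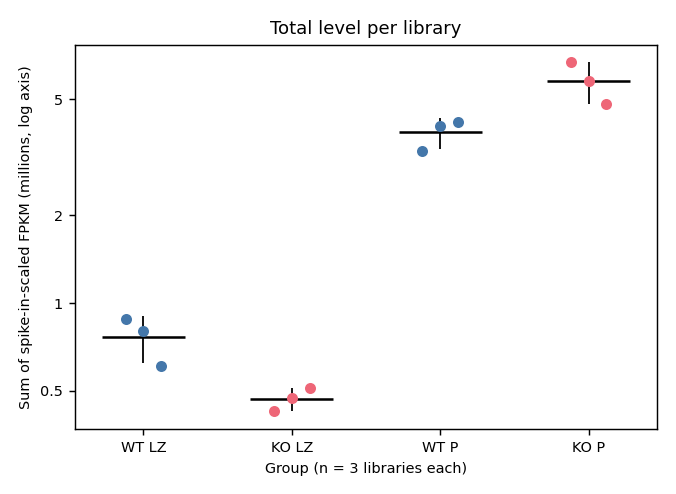
Sum of spike-in-scaled FPKM over 15400 genes per library on a log axis, for the 4 groups (LZ, leptotene/zygotene; P, pachytene; KO, KO-labelled). Points are libraries, horizontal lines group means and vertical lines SD (n = 3). The KO-labelled mean is 0.615 times the WT mean at LZ and 1.5 times at pachytene.

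Rnaseh1, the gene named by the knock-out labels, was present in the libraries of both genotypes. At LZ it was 17.8 ± 2.39 in WT and 14.7 ± 3.62 in KO-labelled libraries, a log2 change of -0.28 (SE 0.23, adjusted p = 0.407 by limma). This change was -0.18 without WT replicate 2, -0.10 without KO-labelled replicate 1 and -0.44 without KO-labelled replicate 2. It turned to 0.29 after median-ratio scaling, 0.37 after quantile normalisation and 0.29 before the spike-in scaling, none of them called. At pachytene it was 53.7 ± 2.74 in WT and 80.2 ± 13.0 in KO-labelled libraries, a log2 change of 0.56 (SE 0.23, adjusted p = 0.0638). All 3 KO-labelled pachytene libraries, at 68.9 to 94.3, lay above the WT libraries, at 51.7 to 56.8. A pseudocount of 5 brought the pachytene change to an adjusted p of 0.0383. Between the stages in WT its log2 change was 1.55 (SE 0.23, adjusted p = 2.71e-05), -0.09 relative to the median of all genes and -0.45 after median-ratio scaling. Before the spike-in scaling it was -0.67 and called lower (adjusted p = 0.0392). On FPKM before the spike-in scaling the pachytene means were 12.6 ± 0.956 and 12.3 ± 4.07, a log2 change of -0.07, and it was 0.20 after median-ratio scaling and 0.24 after quantile normalisation. The level of Rnaseh1 had been planned as a check of the labels, and it was not called lower in KO-labelled libraries at either stage. Which part of the gene was deleted is not known here. A value per gene would include exons outside such a part, so these levels neither bear out nor refute the genotype labels. The directions below are those between labels.

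The first comparison, pachytene against LZ in WT, describes the stage change in the unmodified cells. Some genes of the piRNA pathway rose beyond the median of all genes. Piwil1, which binds pachytene piRNAs, went from 22.7 ± 5.83 to 800 ± 171, a log2 change of 5.09 (SE 0.24), 3.45 above the median. Tdrd5, a piRNA biogenesis factor, went from 19 ± 2.92 to 342 ± 89.1. Some genes of the start of meiosis fell. The recombinase Dmc1 went from 60.2 ± 10.4 to 19.9 ± 3.75, the protease Prss50 from 400 ± 70.3 to 77.9 ± 22.0, cyclin B3 (Ccnb3) from 13.7 ± 0.918 to 3.60 ± 1.12 and the X-linked homeobox gene Esx1 from 40.8 ± 16.3 to 4.0 ± 3.38. Others with the lowest changes were Gal3st1, which sulfates the testis lipid seminolipid, the histone gene Hist1h4m, the X-linked homeobox gene Rhox13 and Cd3e, a subunit of the T cell receptor. The median log2 change of all genes was 1.64, and 12530 of 15400 genes were called, 12455 higher and 75 lower. After median-ratio scaling the split was 3111 higher and 2780 lower. The 8 genes with the highest changes included markers of testis cells other than spermatocytes. Insl3, a Leydig cell hormone, went from 9.87 ± 6.02 to 5710 ± 3233, Cyp17a1, an enzyme of androgen synthesis, from 0.0513 ± 0.0556 to 202 ± 74.7, and smooth muscle actin (Acta2) from 0.283 ± 0.217 to 160 ± 59.7. Akr1cl, Ccl8, Lcn2, Fabp3 and Dcn had log2 changes of 6.91 to 7.77.

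Of 39 genes of the pachytene and A-MYB list, 38 rose (38 adjusted over the list alone, 27 after median-ratio scaling). The list lay 1.41 above the median of all genes (camera adjusted p = 1.62e-05; adjusted p = 0.642 with an estimated correlation). Of 30 piRNA pathway genes, 28 rose (28 adjusted over the list alone, 15 after median-ratio scaling, with 4 lower there), among them Tdrd1 and Pld6, with camera adjusted p = 0.00299 and adjusted p = 0.642 with an estimated correlation. Of 78 OXPHOS genes, 76 rose (76 adjusted over the list alone). After median-ratio scaling 34 rose and 7 fell, and the camera adjusted p was 2.72e-08 (adjusted p = 0.666 with an estimated correlation). The testis forms Cyct, Cox8c and Cox6b2 led the list, with log2 changes of 4.02, 3.77 and 3.42. Of 24 leptotene and zygotene genes, 5 fell and 11 rose (the same counts adjusted over the list alone), and 16 fell with 0 rising after median-ratio scaling. This list lay -1.20 from the median of all genes (camera adjusted p = 8.49e-10; adjusted p = 0.166 with an estimated correlation). All 17 Leydig genes rose (17 adjusted over the list alone, 16 after median-ratio scaling; camera adjusted p = 0.00791 and adjusted p = 0.627 with an estimated correlation). Of 20 blood and macrophage genes 19 rose (19 adjusted over the list alone, 11 after median-ratio scaling; camera adjusted p = 0.391), and Lyz2 went from 3.53 ± 5.45 to 264 ± 198.

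The X and Y chromosomes lagged behind the autosomes between the stages. The median log2 change of 612 X-linked genes was 0.71, or -0.96 relative to autosomal genes, and that of 9 Y-linked genes was -0.38, or -2.06 relative to autosomal genes. On the X, 262 genes rose and 25 fell (219 and 20 adjusted over the list alone), against 12085 and 48 of 14644 autosomal genes. After median-ratio scaling 13 X-linked genes rose and 285 fell. Camera gave an adjusted p of 2.33e-33 for the X chromosome (adjusted p = 0.0744 with an estimated correlation) and 6.25e-12 for the Y chromosome (adjusted p = 0.0744 with an estimated correlation). The X-linked share of the summed FPKM was 1.92% ± 0.205 in WT LZ and 0.703% ± 0.0765 in WT pachytene libraries (exact permutation p = 0.1). Of the 31 X-linked reporters 4 fell and 6 rose (1 and 4 adjusted over the list alone), and 25 fell after median-ratio scaling (camera adjusted p = 3.36e-21; adjusted p = 0.0744 with an estimated correlation). Ddx3x and Pdha1 were among the 6, with log2 changes of 1.77 and 1.44 that turned to -0.04 and -0.39 after median-ratio scaling. Of the retrogenes active at pachytene, autosomal copies such as Pdha2 and Cetn1, 10 of 11 rose (10 adjusted over the list alone, 5 after median-ratio scaling; camera adjusted p = 0.0596).

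Pachytene was compared with LZ in the KO-labelled libraries as well. The sum per library rose 12.2-fold, against 5.03-fold in WT, and 12266 genes were called, 11830 higher and 436 lower, around a median log2 change of 2.29. After median-ratio scaling 4786 were higher and 4577 lower. All 17 Leydig genes rose here as well (17 adjusted over the list alone, 12 after median-ratio scaling; camera adjusted p = 0.133). The X chromosome lay -2.49 from the autosomes, with 176 of 612 genes lower and 115 higher (151 and 91 adjusted over the list alone, 452 and 9 after median-ratio scaling). The difference was -1.55 without the filter and -3.09 with a filter of 5. Camera gave the X chromosome an adjusted p of 1.75e-65, and adjusted p = 0.0355 with an estimated correlation. Its share of the summed FPKM was 2.24% ± 0.30 in KO-labelled LZ and 0.262% ± 0.0901 in KO-labelled pachytene libraries (exact permutation p = 0.1).

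KO-labelled against WT at LZ asks what changes before pachytene. Of the 8 genes with the lowest changes, 4 encode protamines or transition proteins of haploid spermatids. The protamines Prm1 and Prm2, which package sperm DNA, went from 10080 ± 4485 to 1294 ± 1145 and from 3386 ± 1723 to 458 ± 484. The transition proteins Tnp1 and Tnp2, which precede the protamines, went from 2871 ± 1398 to 389 ± 313 and from 4325 ± 1700 to 513 ± 373. Their log2 changes were -3.16 to -3.42, against a median of -0.43 over all genes. The lowest change of all 8 was that of the carbonic anhydrase gene Car2, from 41.2 ± 14.2 to 3.21 ± 2.79 (log2 change -3.46, SE 0.46). The others were the lipid acyltransferase gene Agpat2, the kallikrein gene Klk1b8 and the prion-like gene Prnd. The highest change was that of Rnaset2a, a secreted RNase with a close paralog, from 0.0198 ± 0.0122 to 15.9 ± 8.91 (adjusted p = 0.0296). It was not called without the filter, in a fit of the 6 LZ libraries alone, or without WT replicate 1 or 2 or KO-labelled replicate 2 or 3. At pachytene its level differed widely within each group, from 0.00169 to 20.5 in WT and from 0.00921 to 9.34 in KO-labelled libraries. Rnaset2a was followed by Mgst1 and Gsta3, which are glutathione transferases, the sex hormone-binding globulin gene Shbg, the peroxisomal enzyme Phyh, Fxyd1, the troponin gene Tnni3 and the immediate early gene Egr1. These 7 had log2 changes of 1.13 to 1.57, or 1.56 to 2.01 relative to the median. For each gene named as highest or lowest, all 3 libraries of one group lay above all 3 of the other. The loss of the call was not particular to Rnaset2a. In the fit of the 6 LZ libraries alone 0 genes were called, so every gene named here lost its call there. Only 7 genes were called without WT replicate 1 and 4 without WT replicate 2.

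Of the 40 round spermatid genes 19 fell and 0 rose at LZ (39 fell adjusted over the list alone, 0 after median-ratio scaling). Relative to all genes the list lay at -1.33 (camera adjusted p = 1.01e-08; adjusted p = 0.729 with an estimated correlation). After median-ratio scaling its median log2 change was -1.27 (camera adjusted p = 1.94e-09), and those of Prm1, Prm2, Tnp1 and Tnp2 were -2.70, -2.84, -2.58 and -2.73 (SE 0.71, 0.81, 0.69 and 0.67), with adjusted p of 0.0829, 0.101, 0.0864 and 0.07. Of 39 pachytene and A-MYB genes 21 fell (26 adjusted over the list alone, 1 after median-ratio scaling), with the meiotic cyclin Ccna1 going from 83.7 ± 34.4 to 13.5 ± 8.81 and the germ-cell glycolytic enzyme Pgk2 from 171 ± 28.9 to 50.2 ± 30.8. That list lay at -0.53 (camera adjusted p = 3.63e-05; adjusted p = 0.901 with an estimated correlation). Of 29 G2/M and metaphase I genes 10 fell (17 adjusted over the list alone, 0 after median-ratio scaling), among them the kinases Plk1, Aurka and Aurkb (camera adjusted p = 9.53e-04; adjusted p = 0.901 with an estimated correlation). Of 78 OXPHOS genes 11 fell (61 adjusted over the list alone, 0 after median-ratio scaling; camera adjusted p = 5.03e-05, adjusted p = 0.901 with an estimated correlation). After median-ratio scaling the OXPHOS list was not called and the direction of camera turned (adjusted p = 0.908). None of the 24 leptotene and zygotene genes was called over all genes or adjusted over the list alone, and the axis protein gene Sycp3 read 2113 ± 203 in WT and 1530 ± 397 in KO-labelled libraries. Among 38 R-loop factors 4 fell (1 adjusted over the list alone, 0 after median-ratio scaling). These were the RNase H2 subunits Rnaseh2a, Rnaseh2b and Rnaseh2c and the THO complex member Thoc6, and Rnaseh2a went from 164 ± 28.9 to 56.9 ± 14.8. The share of R-loop factors that fell was below that of all genes, of which 1992 of 15400 fell. The R-loop list lay 0.08 above the median of all genes and was not called (camera adjusted p = 0.72). The other lists with at least 3 members lower were replication and S phase (6 of 42), the piRNA pathway (5 of 30), retrogenes (4 of 11), histones (4 of 46), mitochondrial DNA maintenance (3 of 30) and ribosomal proteins (3 of 83, with Rps4x higher). Adjusted over the list alone these counts were 7, 8, 5, 3, 3 and 1, and after median-ratio scaling 0 fell in each of these lists. None of these lists was called by camera on the spike-in scale (lowest camera adjusted p = 0.0728).

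Markers of Sertoli and of peritubular and endothelial cells stood higher relative to other genes in the KO-labelled LZ libraries, with few single genes called. Their median log2 changes were 0.37 and 0.01, against -0.43 over all genes. Those of the Leydig, interferon and stress lists below were 0.03, -0.02 and -0.17. Most of these lists thus differ from other genes mainly by not falling as far. Some members were near 0 in WT LZ libraries, such as Acta2 (0.0382 to 0.452) and Cyp17a1 (0 to 0.110). There log2(value + 1) keeps changes small. The Sertoli list lay 0.80 above the median of all genes (camera adjusted p = 1.28e-12; adjusted p = 0.32 with an estimated correlation). Of its 27 members only Gata1 rose and Trf fell (0 rose and 1 fell adjusted over the list alone), and after median-ratio scaling 3 rose. The peritubular and endothelial list lay 0.45 above the median (camera adjusted p = 1.52e-07; adjusted p = 0.162 with an estimated correlation) with 0 of 19 genes called. The Leydig list lay 0.47 above it (camera adjusted p = 1.77e-05; adjusted p = 0.32 with an estimated correlation), and 1 of 17 genes fell, the prostaglandin synthase gene Ptgds (0 adjusted over the list alone). After median-ratio scaling the Leydig list was not called (camera adjusted p = 0.301). The blood and macrophage list lay -0.24 from the median of all genes (camera adjusted p = 0.39), with 0 of 20 genes called over all genes or adjusted over the list alone. Without WT replicate 1 this list lay at 0.27 (camera adjusted p = 0.00451). The stress and immediate early list lay 0.26 above the median of all genes (camera adjusted p = 9.25e-07; adjusted p = 0.433 with an estimated correlation), with Ier3 and Egr1 higher and the chaperone gene Dnajb1 lower (1 and 1 adjusted over the list alone). The interferon response list lay 0.41 above that median (camera adjusted p = 3.53e-04; adjusted p = 0.162 with an estimated correlation), with 1 of 28 genes lower (0 adjusted over the list alone), the RNA helicase gene Dhx58, and after median-ratio scaling the list was not called (camera adjusted p = 0.402). On the X chromosome 4 of 612 genes rose and 26 fell (0 and 1 adjusted over the list alone), and its median lay 0.09 above that of the autosomes (camera adjusted p = 0.00109; adjusted p = 0.901 with an estimated correlation, 0.179 after median-ratio scaling). That difference was 0.06 without WT replicate 2, 0.16 without WT replicate 3, 0.14 without KO-labelled replicate 1 and 0.06 without KO-labelled replicate 2. The stage score was 0.895 ± 0.158 in WT and 0.344 ± 0.408 in KO-labelled libraries (exact permutation p = 0.2).

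At LZ 2013 of 15400 genes were called, 21 higher and 1992 lower. Over all 15400 genes, called or not, 5771 had non-overlapping libraries on the spike-in scale, where chance alone gives 10% of genes. The scaling factors did not overlap either, at 0.705 to 1 in WT and 0.528 to 0.632 in KO-labelled libraries. They shift all genes of a library together, so the excess over 10% is not evidence gene by gene. The count rests on single libraries: it was 7 without WT replicate 1, 4 without WT replicate 2, 2943 without WT replicate 3, 359 without KO-labelled replicate 2 and 89 without KO-labelled replicate 3. It was 0 in a limma fit of the 6 LZ libraries alone, with 4682 genes at an unadjusted p under 0.05, and 166 after median-ratio scaling, with 60 higher and 106 lower.

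KO-labelled against WT at pachytene asks what changes at the later stage. Genes on the X chromosome were lower in KO-labelled libraries while most autosomal genes that were called were higher. Nxf2, an X-linked RNA export gene of germ cells, went from 118 ± 18.3 to 20.9 ± 16.5. Tktl1, a transketolase-like gene, went from 29.7 ± 8.74 to 4.10 ± 4.26, the recombination gene Tex11 from 29.3 ± 5.16 to 4.26 ± 3.43 and the transcription factor gene Taf7l from 109 ± 11.4 to 23.7 ± 18.1. Of 612 X-linked genes 363 fell and 5 rose (403 and 6 adjusted over the list alone, 257 and 0 after median-ratio scaling). Of 14644 autosomal genes 1809 fell and 3748 rose, and 1215 fell and 503 rose after median-ratio scaling. The median log2 change of X-linked genes lay -1.54 from that of autosomal genes (camera adjusted p = 1.72e-43; adjusted p = 0.12 with an estimated correlation). Without any 1 of the 6 libraries this difference was -1.82 to -1.42. Its size depends on the processing: it was -2.07 with a pseudocount of 0.1, -2.04 with a filter of 5, -1.15 after median-ratio scaling, -0.97 without the filter, -0.95 after quantile normalisation, -0.94 with a pseudocount of 5 and -0.87 before the spike-in scaling. The X-linked share of the summed FPKM was 0.703% ± 0.0765 in WT and 0.262% ± 0.0901 in KO-labelled libraries (exact permutation p = 0.1). Of the 31 X-linked reporters 17 fell and 0 rose (20 adjusted over the list alone, 16 after median-ratio scaling; camera adjusted p = 6.47e-12, adjusted p = 0.331 with an estimated correlation). Of 9 Y-linked genes measured 4 fell (7 adjusted over the list alone, 4 after median-ratio scaling; camera adjusted p = 3.71e-05 and adjusted p = 0.356 with an estimated correlation). Of the 8 in the Y-linked list, 3 fell (3 adjusted over the list alone; camera adjusted p = 9.08e-05, adjusted p = 0.357 with an estimated correlation): Ube1y1, Rbmy1a1, which has close copies, and the translation factor gene Eif2s3y.

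**Figure D2:**
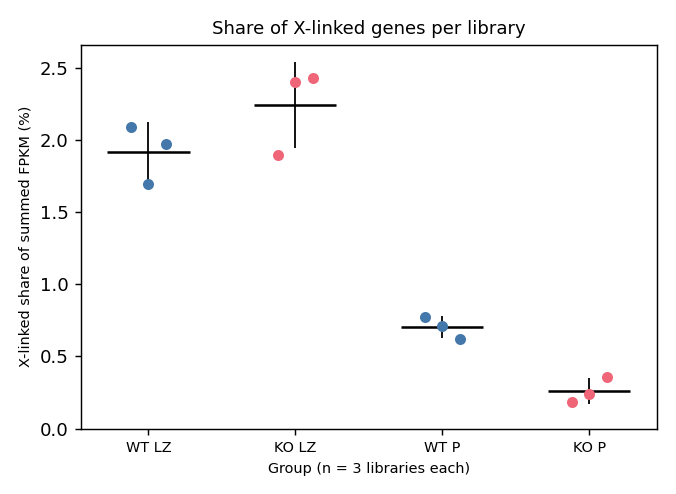
X-linked share of the summed FPKM per library, in percent, for the 4 groups (LZ, leptotene/zygotene; P, pachytene; KO, KO-labelled). Points are libraries, horizontal lines group means and vertical lines SD (n = 3). KO-labelled pachytene libraries lie at 0.184% to 0.360% and WT pachytene libraries at 0.622% to 0.774%.

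Transcripts of late spermatids fell at pachytene too, while some genes of the round spermatid list rose. Prm1 went from 19740 ± 2228 to 3006 ± 1960, Prm2 from 6574 ± 871 to 924 ± 604, Tnp2 from 9072 ± 1702 to 1164 ± 776 and the spermatid kinase Tssk6 from 105 ± 1.55 to 13.4 ± 8.57. Of 40 round spermatid genes 28 fell and 6 rose (30 and 7 adjusted over the list alone, 22 and 0 after median-ratio scaling). The list lay -2.52 from the median of all genes (camera adjusted p = 3.52e-08; adjusted p = 0.678 with an estimated correlation). Among the 6 were Crem, a transcription factor of haploid gene expression, from 578 ± 122 to 953 ± 214, and Dkkl1, an acrosomal protein gene, from 9736 ± 1810 to 16120 ± 3938. Spaca1, of the inner acrosomal membrane, had a log2 change of -1.99 (adjusted p = 0.0107) and the binding protein gene Zpbp one of 0.95 (adjusted p = 0.0171), while the protease gene Acr was not called (log2 change 0.65, SE 0.31, adjusted p = 0.103). Crem, Dkkl1, Spaca1, Zpbp and Acr were chosen here after their values were seen.

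**Figure D3:**
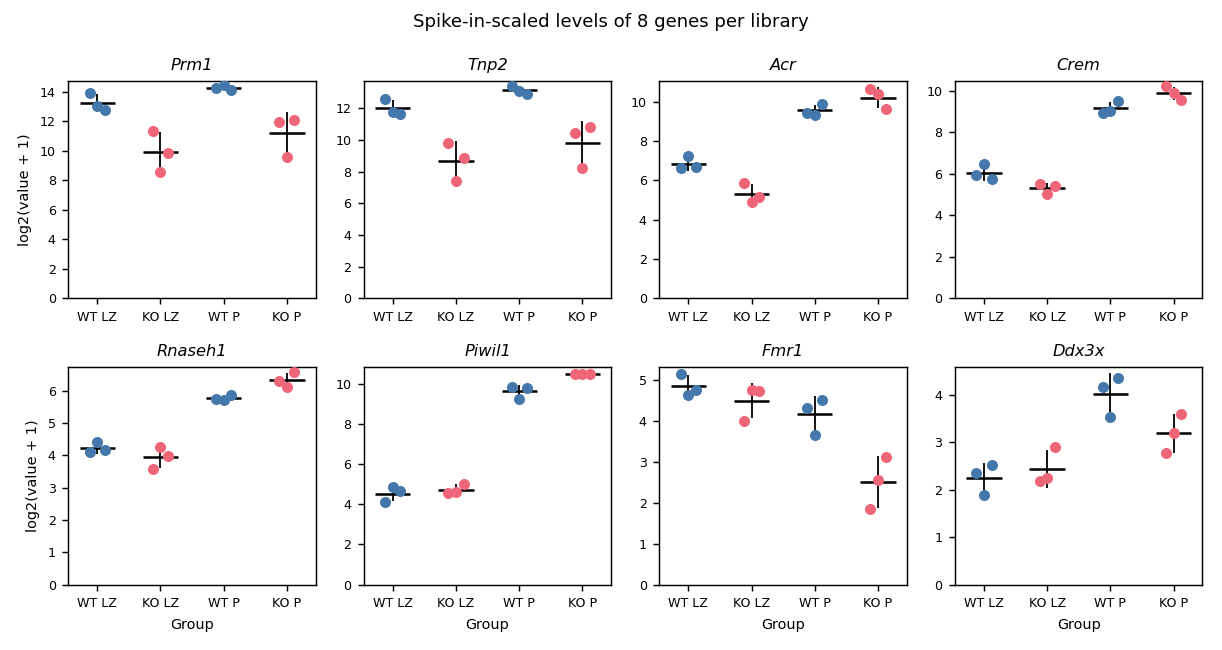
Levels of 8 genes per library as log2(spike-in-scaled FPKM + 1) for the 4 groups (LZ, leptotene/zygotene; P, pachytene; KO, KO-labelled). Points are libraries, horizontal lines means and vertical lines SD of the log2 values (n = 3). Prm1 and Tnp2 lie lower in KO-labelled libraries at both stages, Crem lies lower at LZ and higher at pachytene (log2 changes -0.74 and 0.72, the first not called), and of the X-linked genes Fmr1 lies lower in KO-labelled libraries at pachytene (log2 change -1.65, chosen after its values were seen) while Ddx3x was not called there.

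Many genes of pachytene spermatocytes rose, and of the spermatogonia genes more fell than rose. Of 39 pachytene and A-MYB genes 24 rose and 1 fell (29 and 2 adjusted over the list alone, 9 and 1 after median-ratio scaling), the one being the chaperone gene Calr3. Ybx3 (listed as Csda), which binds germ-cell mRNA, went from 3590 ± 872 to 8330 ± 1166, and Tcfl5, a transcription factor of pachytene cells, from 653 ± 141 to 1508 ± 216. The list lay 0.50 above the median of all genes (camera adjusted p = 1.54e-04; adjusted p = 0.861 with an estimated correlation). Of 24 leptotene and zygotene genes 7 fell and 3 rose (7 and 4 adjusted over the list alone, 8 and 0 after median-ratio scaling; camera adjusted p = 0.0213, adjusted p = 0.866 with an estimated correlation). Stra8, which starts meiosis, went from 93.4 ± 22.2 to 22.1 ± 19.2 with 1 KO-labelled library at 0, and the cohesin gene Rec8 from 14.3 ± 2.97 to 3.44 ± 1.66. Of 27 spermatogonia genes 15 fell and 3 rose (15 and 3 adjusted over the list alone, 13 and 2 after median-ratio scaling). Dmrt1 went from 51.9 ± 14.2 to 7.09 ± 5.09 and Sohlh1 from 42.5 ± 2.92 to 6.15 ± 4.81, both transcription factors of spermatogonia (camera adjusted p = 5.01e-07; adjusted p = 0.331 with an estimated correlation). The stage score was 3.48 ± 0.0955 in WT and 4.66 ± 0.651 in KO-labelled libraries, a difference of 1.18 (exact permutation p = 0.1).

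Markers of somatic cells moved in different directions at pachytene. Of 19 peritubular and endothelial genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, 7 and 0 after median-ratio scaling), and Acta2 went from 160 ± 59.7 to 25.8 ± 6.04 (camera adjusted p = 5.01e-07; adjusted p = 0.179 with an estimated correlation). Of 27 Sertoli genes 9 fell and 0 rose (8 fell adjusted over the list alone, 11 after median-ratio scaling). Tsc22d3 led that list, from 96.3 ± 6.79 to 18.8 ± 10.5 (camera adjusted p = 3.52e-05; adjusted p = 0.678 with an estimated correlation). Of 17 Leydig genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, 1 and 0 after median-ratio scaling; camera adjusted p = 0.735), with the luteinizing hormone receptor Lhcgr going from 6.13 ± 5.0 to 19.6 ± 7.25. Of 20 blood and macrophage genes 1 rose, Ptprc, and 1 fell, the erythroid gene Alas2 (1 and 1 adjusted over the list alone, 0 and 0 after median-ratio scaling; camera adjusted p = 0.983).

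The 8 highest genes included Serpina1e, a protease inhibitor of a family with near-identical members, from 0.0918 ± 0.159 to 21.4 ± 4.34 (log2 change 4.35, SE 0.25). Serpind1, which encodes heparin cofactor II, went from 0.0971 ± 0.0857 to 10.1 ± 0.766, and the amino acid transporter gene Slc1a4 from 0.887 ± 0.175 to 16.3 ± 2.33. Fam23a, Mylk3, the chemokine genes Ccl2 and Cxcl10 and Ccdc109b, a regulator of mitochondrial calcium uptake, followed with log2 changes of 2.42 to 2.86. The 8 lowest were Tmsb15l, Rmnd1, a gene of mitochondrial translation, Gng13, Cypt14, Prnd, Phlda2, Upp1 and Cdca7, with log2 changes of -4.25 to -3.52. Phlda2, an imprinted gene, was listed at 0 in all 3 KO-labelled pachytene libraries and at 10.6 ± 1.73 in WT.

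Among genes of the meiotic machinery and of R-loop handling more rose than fell, around a median of all genes of 0.37, and few were called after median-ratio scaling. Of 47 meiotic recombination genes 19 rose and 4 fell (21 and 4 adjusted over the list alone, 1 and 5 after median-ratio scaling; camera adjusted p = 0.164). The 4 were Tex11, Dmc1, Rad51ap2 and Mnd1, and Dmc1 went from 19.9 ± 3.75 to 6.62 ± 3.79. Of 25 synaptonemal complex and axis genes 8 rose and 3 fell (9 and 3 adjusted over the list alone, 0 and 3 after median-ratio scaling; camera adjusted p = 0.569). The 3 were the cohesin genes Rec8, Rad21l and Smc3. Of 38 ATR and DNA damage response genes 12 rose and 1 fell, the X-linked Scml2 (12 and 1 adjusted over the list alone, 2 and 2 after median-ratio scaling; camera adjusted p = 0.214), and H2afx, the histone variant marked at DNA breaks, went from 310 ± 66.7 to 566 ± 87.1. Of 38 R-loop factors 19 rose and 0 fell (19 adjusted over the list alone), and 2 rose and 1 fell after median-ratio scaling. Tdrd3 went from 97.2 ± 24.8 to 219 ± 32.6, and the helicase gene Rtel1 from 41.2 ± 0.995 to 78.7 ± 8.73. That list lay 0.20 above the median (camera adjusted p = 0.0213; adjusted p = 0.892 with an estimated correlation, 0.0645 after median-ratio scaling). Of 28 p53 targets 3 rose and 4 fell (3 and 3 adjusted over the list alone, 0 and 4 after median-ratio scaling; camera adjusted p = 0.411), among them the death effector Bax, from 72.7 ± 14.1 to 31.1 ± 8.41. Of 30 piRNA pathway genes 15 rose and 5 fell (17 and 5 adjusted over the list alone, 3 and 5 after median-ratio scaling; camera adjusted p = 0.233), with Tex15 at 19 ± 4.03 in WT and 4.87 ± 2.2 in KO-labelled libraries.

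Among mitochondrial and ribosomal genes, too, more rose than fell on the spike-in scale. Of 78 OXPHOS genes 29 rose and 5 fell (33 and 5 adjusted over the list alone, 0 and 6 after median-ratio scaling), with the somatic cytochrome c gene Cycs lower, from 288 ± 34.8 to 116 ± 34.1. The list lay 0.17 above the median of all genes (camera adjusted p = 0.00576; adjusted p = 0.906 with an estimated correlation, 0.123 after median-ratio scaling) and -0.24 from it after quantile normalisation. Of 83 ribosomal protein genes, a family with many close copies, 40 rose and 2 fell (44 and 3 adjusted over the list alone, 3 and 4 after median-ratio scaling). That list lay 0.22 above the median (camera adjusted p = 1.6e-04; adjusted p = 0.906 with an estimated correlation), was called higher after median-ratio scaling as well (camera adjusted p = 0.00111) and lay at -0.17 after quantile normalisation. Of 30 genes of mitochondrial DNA maintenance 7 rose and 3 fell (2 and 3 adjusted over the list alone, 0 and 4 after median-ratio scaling; camera adjusted p = 0.409). The 3 were Fen1, Top1mt and Tfam, which packages mitochondrial DNA and went from 45.0 ± 2.60 to 16.4 ± 4.35. Of 11 retrogenes 6 rose and 0 fell (7 and 1 adjusted over the list alone, 1 and 0 after median-ratio scaling; camera adjusted p = 0.144).

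Among cell cycle genes, 13 of 42 replication and S phase genes rose and 5 fell (13 and 5 adjusted over the list alone, 2 and 6 after median-ratio scaling; camera adjusted p = 0.84), and the helicase subunit gene Mcm2 went from 21.4 ± 5.05 to 2.51 ± 2.04. Of 29 G2/M and metaphase I genes 9 rose and 3 fell (9 and 3 adjusted over the list alone, 0 and 2 after median-ratio scaling; camera adjusted p = 0.409), with the meiotic kinase gene Aurkc at 290 ± 79.2 in WT and 739 ± 264 in KO-labelled libraries. Of 28 interferon response genes 7 rose and 0 fell (5 adjusted over the list alone, 0 and 0 after median-ratio scaling; camera adjusted p = 0.352), led by Cxcl10, from 1.34 ± 1.83 to 9.57 ± 2.17. Of 39 stress and immediate early genes 11 rose and 6 fell (13 and 6 adjusted over the list alone, 3 and 5 after median-ratio scaling; camera adjusted p = 0.483), with Chac1, a glutathione-degrading enzyme of the stress response, going from 2.16 ± 1.44 to 14.1 ± 1.03. Of 37 spermatogenesis transcription factors 16 rose and 9 fell (19 and 11 adjusted over the list alone, 2 and 8 after median-ratio scaling; camera adjusted p = 0.569). Of 46 histone genes, a family with near-identical members, 6 rose and 9 fell (5 and 6 adjusted over the list alone, 3 and 5 after median-ratio scaling; camera adjusted p = 0.352). The spermatid variants H2afb1 and H1fnt were among the 9. The median, the mean and the direction of camera differed in sign for the synaptonemal complex, transcription factor and blood and macrophage lists at pachytene. At LZ they did so for the recombination, synaptonemal complex, ATR, R-loop, ribosomal, transcription factor, histone and blood and macrophage lists and for the Y chromosome.

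**Figure D4:**
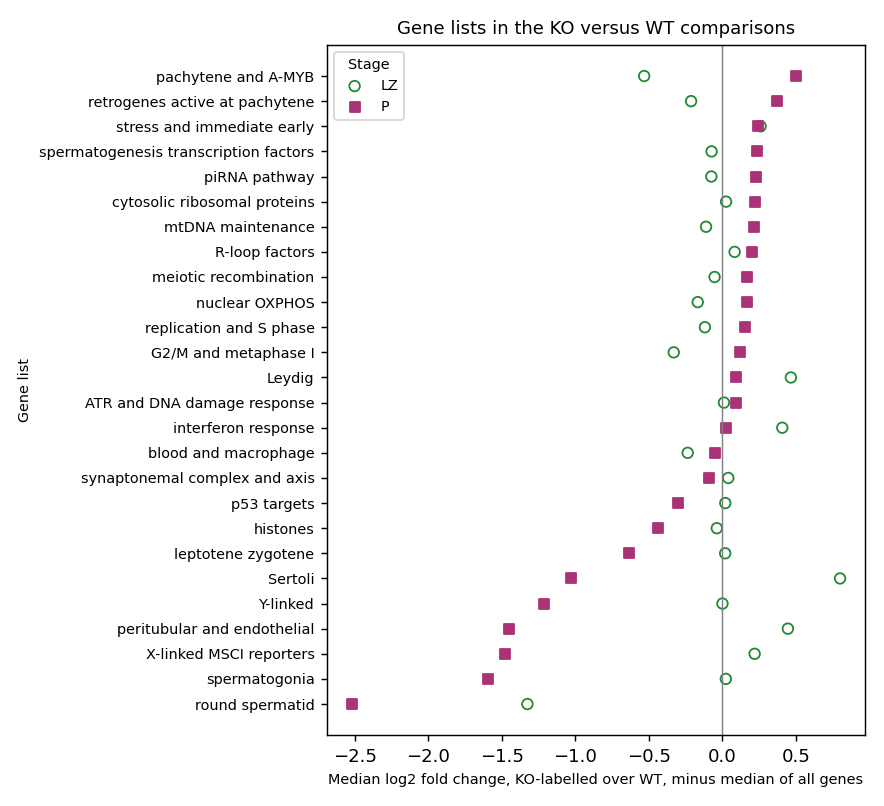
Median log2 change of each gene list between KO-labelled and WT libraries minus the median of all genes, at LZ (open circles) and at pachytene (P, filled squares). Each point is 1 list and has no error bar. The round spermatid list lies at -1.33 and -2.52, the X-linked reporters at 0.22 and -1.48 and the pachytene and A-MYB list at -0.53 and 0.50.

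At pachytene 5980 of 15400 genes were called, 3784 higher and 2196 lower. Over all 15400 genes, called or not, 8387 had non-overlapping libraries on the spike-in scale, where chance alone gives 10% of genes. Here too the scaling factors did not overlap, at 3.91 to 4.91 in WT and 5.55 to 7.82 in KO-labelled libraries, so the excess is not evidence gene by gene. After median-ratio scaling 505 were higher and 1491 lower, and on FPKM before the spike-in scaling 42 were higher and 1727 lower. The majority direction turned when any of 4 libraries was left out. Without WT replicate 1, 926 genes were higher and 1174 lower (2100 called). Without WT replicate 2, 762 were higher and 1299 lower (2061 called). Without KO-labelled replicate 1, 286 were higher and 1075 lower (1361 called). Without KO-labelled replicate 2, 357 were higher and 985 lower (1342 called).

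Whether the KO effect differed between the stages was tested as an interaction, and 5919 genes were called, 5381 with a higher and 538 with a lower KO effect at pachytene. The median difference was 0.72 over all genes. Crisp2, a secreted protein of sperm, was at 505 ± 91.9 in WT and 198 ± 30.6 in KO-labelled LZ libraries, and at 4860 ± 777 and 9890 ± 2112 at pachytene (difference 2.36, SE 0.32, adjusted p = 0.00493). Bgn, a proteoglycan of connective tissue, was at 33.5 ± 4.82 in WT and 7.65 ± 0.478 in KO-labelled pachytene libraries, with 0.170 ± 0.224 and 0.502 ± 0.315 at LZ. Of 39 pachytene and A-MYB genes 32 had a higher effect at pachytene (32 adjusted over the list alone, 6 after median-ratio scaling; camera adjusted p = 1.23e-06, adjusted p = 0.62 with an estimated correlation). On the X chromosome 143 of 612 genes had a lower effect and 5 a higher one (92 and 3 adjusted over the list alone, 169 and 2 after median-ratio scaling; camera adjusted p = 1.08e-45, adjusted p = 0.0522 with an estimated correlation). Of the 40 round spermatid genes 8 had a higher effect at pachytene and 0 a lower one (7 and 0 adjusted over the list alone, 2 and 0 after median-ratio scaling). The median of that list lay the other way, at -0.90 relative to all genes, as did the direction of camera (adjusted p = 0.0569). After median-ratio scaling 353 genes had a higher and 676 a lower effect. Without KO-labelled pachytene replicate 1, 3748 genes were called.

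Averaged over the stages, 109 genes were higher and 1880 lower in KO-labelled libraries, and of the round spermatid genes 30 of 40 were lower and 0 higher (31 and 0 adjusted over the list alone, 27 and 0 after median-ratio scaling; camera adjusted p = 1.03e-13, adjusted p = 0.495 with an estimated correlation). On the X chromosome 277 of 612 genes were lower and 1 higher (370 and 2 adjusted over the list alone, 158 and 1 after median-ratio scaling; camera adjusted p = 2.45e-25, adjusted p = 0.462 with an estimated correlation). After median-ratio scaling 421 genes were higher and 1133 lower. Of the genes lower at LZ and at pachytene, 371 were shared against 284.1 by independence (odds ratio 1.45, Fisher's exact p = 7.38e-09), and without the filter the odds ratio was 1.08 (Fisher's exact p = 0.499). Another 701 genes were lower at LZ and higher at pachytene, against 489.5 by independence (Fisher's exact p = 4.64e-30). After median-ratio scaling these counts were 19 against 10.26 (Fisher's exact p = 0.00757) and 0 against 3.476 (Fisher's exact p = 0.052). Both contrasts use the same variance estimate of each gene, and genes are not independent, so the p of these overlaps do not show a shared effect. Across genes, which are not independent replicates, the log2 changes of the stages had a Pearson r of 0.179. The median, the mean and the direction of camera differed in sign for the blood and macrophage, synaptonemal complex, p53 and mitochondrial DNA maintenance lists in this average. They did so for the blood and macrophage, transcription factor and interferon lists in the interaction, for the ATR, mitochondrial DNA maintenance and interferon lists in the WT stage comparison, and for the replication, transcription factor and interferon lists in the KO-labelled one.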

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

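The tests of a later mean stage, of counting error in the spike-ins and of the spike-in scaling, the repeat before that scaling, the bound in the test of a general loss of other cell types at pachytene, and the test of that loss at LZ, were chosen only after the result was seen. The KO effect differed between LZ and pachytene for 5919 genes in the interaction contrast of limma. X-linked genes had an interaction median of -1.56 relative to autosomal genes, which was -1.92 with a pseudocount of 0.1, -1.87 with a filter of 5, -1.18 after median-ratio scaling, -1.01 with a pseudocount of 5, -0.96 without the filter, -0.94 after quantile normalisation and -0.92 before the spike-in scaling. By camera with the preset correlation, 7 lists differed on the spike-in scale and after median-ratio scaling, though none with an estimated correlation, with interaction medians relative to all genes of -0.61 for leptotene and zygotene, 1.05 for pachytene and A-MYB, -1.55 for spermatogonia, -1.82 for Sertoli cells, -1.84 for peritubular and endothelial cells, -1.64 for the X-linked reporters and -1.23 for the Y-linked list. The genes with the smallest p had interaction log2 changes of 4.02 (Serpina1e), 2.99 (Serpind1), 2.74 (Mylk3), 2.36 (Crisp2), 2.26 (Efcab10), -2.89 (Ly6g6e), -2.43 (Cml5), -2.34 (Bgn), -2.63 (Xlr3a) and -2.49 (Cnn1). Of 162 named genes called in a KO-labelled against WT comparison, 102 were also called in the interaction. The ratio of the summed level between KO-labelled and WT libraries was 0.615 at LZ and 1.5 at pachytene, with every library on the opposite side, and the difference between these ratios was not tested. In 100 splits of the libraries within each stage, only the real one gave as many interaction genes and the highest other gave 2324. This argues against a random grouping of these libraries but does not exclude it. The splits exchange genotypes within stages, so they test for any genotype effect and not for a difference between the stages.

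X-linked genes were lower in KO-labelled pachytene libraries. They lay -1.33 from autosomal genes matched on the mean level over all 12 libraries (lowest -1.44 and highest -1.18 in 1000 draws). This argues against a general loss of genes low on that mean. The median X-linked level over the median autosomal level was 0.613 in WT LZ but 0.273 in WT pachytene libraries. The matched genes thus need not be alike in level at pachytene, and a loss of genes low at that stage stays open. LZ cells in the WT pachytene libraries stay open, because the test of the share of LZ RNA they would need cannot decide. It used genes with a share of the RNA at least 4 times higher in LZ than in KO-labelled pachytene libraries, so genes taken for being low in a group under test. By it 1461 autosomal genes needed 1.26 times the share that 192 of the 612 X-linked genes needed (bootstrap interval 1.08 to 1.44), and 11 members of the leptotene and zygotene list 0.375 times (0.196 to 0.871). A later mean stage of the KO-labelled cells also stays open, as a candidate explanation, with a stage score higher by 1.18 (exact permutation p = 0.1). None of these open explanations can be told apart from stronger silencing of the X chromosome in cells labelled knock-out, which was not tested.

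The summed level was lower at LZ and higher at pachytene in KO-labelled libraries. Before the spike-in scaling the ratios of the sums were 0.938 and 0.954, so the difference lies in the scaling factors, but FPKM fixes such sums within narrow limits and the test cannot decide. If the whole numbers behind the factors are spike-in read counts, their sums of 605 in WT and 906 in KO-labelled LZ libraries and of 121 and 78 at pachytene differ beyond counting error (exact binomial p = 9.71e-15 and 0.00281). Their unit is unknown, so counting error stays open. Unequal cell numbers, spike-in amounts or depth and a change in RNA per cell cannot be told apart, because neither these amounts nor the scaling formula is stated.

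Late haploid genes were lower in KO-labelled libraries of both stages. A loss of every other testis cell type alike was examined through gaps between lists. At pachytene 15 of 27 spermatogonia genes fell and 3 rose by limma, while 2 of 17 Leydig genes fell and 5 rose. The intervals of the gaps resample genes and not libraries. Estimated correlations within these lists were 0.215 to 0.545, so the intervals do not measure the spread between libraries. The gaps alone therefore cannot exclude a loss alike. At pachytene the Leydig list lay 1.69 above the spermatogonia list (bootstrap interval over genes 0.456 to 2.48), and 1.00 after median-ratio scaling (0.231 to 1.85). The interval misses the bound of 0.5 that was set first, which was too strict, since a loss alike allows no gap beyond the spread. With intervals widened for 6 pairs, this gap after median-ratio scaling included 0 (-0.136 to 2.09). At pachytene 3 of the 6 pairs of the 4 lists compared below lay apart on both scales by such intervals. Among them, blood and macrophage lay 0.98 above Sertoli genes (0.568 to 1.53), and 0.92 after median-ratio scaling (0.499 to 1.51). At LZ the gap between the Leydig and spermatogonia lists was 0.44 (0.141 to 0.714) but 0.21 after median-ratio scaling (-0.155 to 0.799). There 3 of the 6 pairs among the Leydig, blood and macrophage, Sertoli and spermatogonia lists lay apart on both scales, with intervals widened for 6 pairs. These include the pairs of blood and macrophage with Leydig and with Sertoli genes. The LZ median of the blood and macrophage list, relative to all genes, turned from -0.24 to 0.27 without WT replicate 1. Sertoli lay 0.78 above spermatogonia genes (0.187 to 1.12), and 0.99 after median-ratio scaling (0.389 to 1.31). At pachytene the median log2 changes were 0.47 for Leydig, 0.32 for blood and macrophage, -0.66 for Sertoli and -1.22 for spermatogonia genes. A single source of spermatid RNA, with less of it in KO-labelled libraries, stays open as a candidate explanation, and the cells had been sorted. Over the 32 of 40 round spermatid genes that were lower at both stages before the spike-in scaling, the log2 ratio of the losses had an interquartile range of 1.19, but these losses follow the level of each gene and the genes were taken for being lower, so the test cannot decide. The most abundant transcripts, Prm1 and Tnp2, were at 10080 and 4325 in WT LZ libraries. Fewer spermatids in the testes of animals labelled knock-out, a different gate and different washing stay open too and were not tested.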

How the results depend on the processing

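The repeat on FPKM before the spike-in scaling was chosen only after the result was seen. Of the alternatives to named genes, 4399 counted as unchanged, 951 lost the call, 12 gained it and 15 reversed. For lists the numbers were 1627, 117, 78 and 24. A change of direction counted as a reversal only with a call in either fit. Changes of sign without a call, such as that of Rnaseh1 at LZ, are among the unchanged. Genes called at LZ, 2013 as reported, were 1108 with a pseudocount of 5, 904 without the filter, 166 with median-ratio scaling, 188 with quantile normalisation, 273 before the spike-in scaling, 0 with only the 6 libraries compared (4682 at an unadjusted p under 0.05), 5189 with library weights, 1300 at 2-fold or more, and 4 to 2943 when each library was left out (4 without WT replicate 2, 7 without WT replicate 1, 89 without KO-labelled replicate 3, 359 without KO-labelled replicate 2). At pachytene they were 1996, 1247 and 1769 under the 3 scalings in the same order, 9434 with weights, 2741 at 2-fold or more and 1342 to 6915 when each library was left out (2100 without WT replicate 1, 2061 without WT replicate 2, 1361 without KO-labelled replicate 1, 1342 without KO-labelled replicate 2). The WT stage comparison gave 5891, 5845 and 6033 under those scalings, and the interaction 1029, 360 and 986, and 3748 to 6443 when each library was left out (3748 without KO-labelled pachytene replicate 1). The average over stages gave 3257 with weights and 1266 at 2-fold or more. Ratios of summed level at LZ, at pachytene and between WT stages were 0.937, 1.16 and 1.22 with median-ratio scaling, 1, 1 and 1 with quantile normalisation, which fixes them, and 0.938, 0.954 and 1.02 before the spike-in scaling. The stage score difference at pachytene was 0.71 with quantile normalisation. The log2 change of Rnaseh1 at pachytene was 0.53 with a pseudocount of 5. The X-linked minus autosomal median at LZ was no longer called with an estimated correlation (0.087, p = 0.351), median-ratio scaling (0.091, p = 0.0894), quantile normalisation (0.076, p = 0.277) or before the spike-in scaling (0.086, p = 0.071), each p by camera; at pachytene its p with an estimated correlation was 0.00428 before adjustment over the lists. The odds ratio of the overlap was 1.08 without the filter. The cause of these changes was not tested, apart from the smaller number of libraries and the fixed sums.

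Reversals in the WT stage comparison were, with median-ratio scaling, Rnaseh1 -0.45, Cst12 -0.26, Gstm6 -0.24, Ddx3x -0.043, Pdha1 -0.39, interferon list 0.52 and ribosomal list -0.21. With quantile normalisation they were Rnaseh1 -0.41, Cst12 -0.58, Gstm6 -0.40, Pdha1 -0.19, synaptonemal complex -0.61, interferon 0.45 and ribosomal -0.55. Before the spike-in scaling they were Rnaseh1 -0.67, Stag3 -0.014, Cst12 -0.51, Gstm6 -0.48, Ddx3x -0.24, Pdha1 -0.56, interferon 0.60 and ribosomal -0.20. The ribosomal list also reversed there with a pseudocount of 0.1 (-0.15) and a filter of 5 (-0.068), and the round spermatid list with a pseudocount of 5 (0.19) and no filter (0.21). At LZ the ribosomal list reversed with a pseudocount of 5 (-0.14), no filter (-0.11) and without WT replicate 3 (-0.069; the highest value with a library left out was 0.14), and the blood and macrophage list without WT replicate 1 (0.27; the lowest was -0.52). At pachytene with quantile normalisation OXPHOS was at -0.24 and ribosomal at -0.17. In the interaction with quantile normalisation synaptonemal complex was at -0.57, R-loop -0.13, OXPHOS -0.19, piRNA -0.37 and ribosomal -0.31, and before the spike-in scaling R-loop was at -0.035 and ribosomal at -0.025. Of the genes, only Rnaseh1 before the spike-in scaling was called in the new direction (adjusted p = 0.0392). The cause of these reversals was not tested.

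The labels give replicate numbers without stating that they pair libraries, and correlations across genes of libraries with one number, after group means were removed, were -0.0112 to 0.201 for WT and KO-labelled LZ and -0.183 to 0.0796 at pachytene. Between stages they were 0.0351 to 0.16 in WT, where 3 of 3 libraries were closest to the one with their own number, and 0.0924 to 0.261 in KO-labelled libraries, where 2 of 3 were, so pairing between stages is not excluded. With the number as a replicate block 2095 genes were called at LZ, 5398 at pachytene, 12742 in the WT stage comparison, 12383 in the KO-labelled one, 5439 in the interaction and 2086 in the average. With genotype and number as the block these were 12939 in the WT stage comparison, 12548 in the KO-labelled one and 4863 in the interaction. Depth is unknown, so what it limits is not stated.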

Other observations

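The tests of other splits of the libraries were chosen before their results were seen, and the levels of single genes were chosen after. RNA of other testis cells was present in the sorted pachytene libraries of both genotypes. Insl3, the Leydig cell hormone, was at 5710 ± 3233 in WT pachytene libraries, and Lyz2, a macrophage gene, at 264 ± 198. The score of the round spermatid list minus the pachytene and A-MYB list was 0.29 in WT and -0.59 in KO-labelled LZ libraries (exact permutation p = 0.2), and -0.97 and -3.26 at pachytene (exact permutation p = 0.1). KO-labelled LZ replicate 2 had the lowest correlations with the other libraries of its group, at 0.923 and 0.946, against 0.952 between replicates 1 and 3. KO-labelled LZ replicate 1 correlated more with each WT LZ library, at 0.963 to 0.97, than with its own group, and its stage score of 0.81 lay within the WT values of 0.79 to 1.08. Its summed level of 426110 lay with its own group, below the lowest WT value of 608190.

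Groupings of the libraries other than the real one were fitted in limma to all 12 libraries, with the 6 libraries of a comparison regrouped in each of 10 splits. These splits are too few for a share under 0.05. At LZ the real split gave 2013 genes and the highest other 3, at pachytene 5980 and 3, between the WT stages 12530 and 1, and between the KO-labelled stages 12266 and 0, so in each only 1 of the 10 splits gave as many. For the KO effect averaged over the stages, 2 of 100 splits within stages, the real one among them, gave as many as the real 1989 genes. This share is under 0.05, which argues against a random grouping of these libraries but does not exclude it. The other split gave 5919 genes. It exchanges the genotype labels in a single stage, which turns the average into the interaction.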
